A study of Mus musculus with 8 samples.

How the data were processed

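RNA bound to tagged ribosomes was purified from midbrain dopaminergic neurons of C57BL/6 mice (translating ribosome affinity purification), so the counts describe ribosome-associated RNA. Per the labels' protocols, the mice received a daily intraperitoneal injection for 5 days of saline or of MPTP-HCl at 30 mg/kg free base, and tissue was collected 4 days after the last injection. Per the labels' protocols, cDNA was amplified from nanogram amounts of RNA with a kit that does not mark strand. It was sheared and sequenced as single-end reads, with a pair of libraries sharing each sequencing run. No fit held the run itself, so if runs followed the groups, run and treatment cannot be told apart. The protocol covers RNA from substantia nigra and ventral tegmental neurons in one sample or in separate samples and does not say which applies to these libraries. The authors' name for the deposited counts includes SN, the usual abbreviation of substantia nigra, but says nothing further on the dissection.

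The authors deposited 1 table of raw counts per gene, with 21761 genes under Entrez identifiers and 8 library columns. Per the submitters' processing notes, TopHat2 2.0.8 and the mm10 genome build were used. The counting tool, the gene annotation and the strand setting are not given in the sources used here, so reads from a gene and an overlapping gene on the other strand cannot be told apart. Of the gene symbols, 27 had been turned into dates and were restored by Entrez identifier from the RefSeq table of GRCm38.p6, and 90 genes without a symbol kept their identifier. The genes without a symbol held between 0.0505% and 0.056% of a library's counts. No mitochondrially encoded gene of the lists was in the table. All 8 library columns matched 1 sample each by title.

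Library totals ranged from 54192354 to 78892061 counts. No pair of libraries within a group agreed within sampling noise, so each was counted as 1 replicate. The labels number the replicates but do not say that they came from separate animals, so the p-values measure only the spread between these samples, which may be technical. The amplified reads carry no molecular identifiers.

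Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by TMM, low genes were removed by the filterByExpr function with the group as argument (15999 genes remained), and MPTP was compared with saline by the robust quasi-likelihood F-test with no covariate. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over all genes tested. Log2 fold changes are MPTP minus saline, and each standard error (SE) was taken as the size of the log2 fold change divided by the square root of F. CPM are counts relative to the TMM-scaled library size, in the usual unit, and log2 CPM used a prior count of 2.

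Gene lists were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, which compares the genes of a list with all other genes. The threshold was an adjusted p of 0.05 over the 48 lists that held at least 5 tested genes. A list score was the mean log2 CPM of its genes in a library. The dopaminergic marker score is that of the dopaminergic neuron list, and the non-neuronal marker score is the mean of the scores of the astrocyte, oligodendrocyte, microglia and endothelial lists. Scores were compared by an exact two-sided permutation test over the 70 ways to choose 4 of the 8 libraries, which cannot give a p below 0.0286.

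The grouping, the tests, the gene lists, the rule for naming genes and most other settings were fixed before the data were examined. The rule names Th, Slc6a3, Slc18a2, Ddc, Aldh1a1, Satb1 and Zdhhc8 in every case. It also names up to 12 genes per direction with the largest log2 fold change among those past the threshold, with a mean log2 CPM of at least 1 and no overlap between the groups, passing over predicted genes and microRNA genes, and up to 4 members with the smallest p from each list described. Mmp12 and Nms fall outside it and were named after their values were seen. Some single-gene results are not reported here.

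Other settings fixed then were DESeq2 size factors, upper quartile scaling, no filter, a mean CPM of at least 5, the replicate number as a block, the non-neuronal score as a covariate, leaving out each library, DESeq2 1.42.0, limma voom with sample weights, camera with an estimated correlation, and fry. Settings that leave out the library saline 3 together with a second change, and 1 list without shared genes, were added after seeing the data. The gene test was tested on simulated counts for 15840 genes with the means and library sizes of these samples. It recovered 59.2% of genes changed 1.5-fold, 78.0% of those changed 2-fold, 87.8% of those changed 4-fold and 93.9% of those changed 8-fold. Of its 171 calls, 14 were false. The simulated genes varied independently, without a shift shared by many genes as in saline 3, so these rates may not hold here. Gene positions are from GENCODE vM21 on GRCm38, the assembly that mm10 names, or from RefSeq where stated. Annotation and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.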

Results

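Ribosome-associated RNA of midbrain dopaminergic neurons was compared between 4 libraries from mice given the neurotoxin MPTP and 4 libraries from mice given saline, 4 days after the last of 5 daily injections. MPTP is converted in the brain to a mitochondrial complex I inhibitor that dopaminergic neurons take up. Totals were 78892061, 72396116, 66450856 and 76082039 counts for MPTP replicates 1 to 4 and 67083649, 69333470, 60146512 and 54192354 counts for saline replicates 1 to 4. Correlations of log2 CPM between libraries lay between 0.965 and 0.980. The first principal component held 20.5% of the variance. On it, saline 3 (-24.1) lay just beyond the MPTP libraries (-23.0 to -15.3), on the side away from the other saline libraries (26.9 to 38.9).

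The design asks how the toxin changes the RNA that dopaminergic neurons translate. A small set of genes known from injured neurons was higher in MPTP. Atf3, a stress-induced transcription factor, went from 0.0582 ± 0.0757 CPM in saline to 7.38 ± 0.629 CPM in MPTP (SD, n = 4 each), a log2 fold change of 7.06 (SE 0.47, adjusted p = 5.1e-07). Its counts were 659, 472, 498 and 572 in the MPTP libraries and 2, 1, 1 and 9 in the saline libraries. With so few saline counts the size is uncertain: the log2 fold change of Atf3 was 8.38 without saline 4, which held the 9 counts, and 6.73 in the lowest alternative. Sprr1a, a growth-associated protein of regenerating axons, rose by a log2 fold change of 6.07 (SE 0.59, adjusted p = 6.8e-05), and Mustn1, a musculoskeletal nuclear protein, by 4.97 (SE 0.28, adjusted p = 6.7e-08). Over the alternatives these ranged from 5.65 to 7.73 and from 4.81 to 6.29. Jun, the partner of Atf3 in AP-1, rose 2.60-fold, from 16.4 ± 1.76 to 42.8 ± 2.55 CPM (SD, n = 4 each, adjusted p = 3.0e-06).

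In all, edgeR's quasi-likelihood test called 12 genes higher and 5 lower in MPTP among 15999 tested, and 1405 genes had an unadjusted p under 0.05. Besides those 4, the higher genes were the membrane peptidase Ecel1 (log2 fold change 3.09), the intermediate filament peripherin Prph (1.40), the pro-apoptotic BH3-only gene Hrk (1.29), the adaptor Sh2d3c (1.10), the microtubule regulator Stmn4 (1.02) and the phosphatase Dusp1 (0.76). Mmp12, a macrophage metalloelastase, and the neuropeptide gene Nms were also higher, with log2 fold changes of 5.29 and 2.97. Both were named after their values were seen, and Mmp12 had only 35 to 146 counts in the MPTP libraries against 0 to 4 in saline. All 17 called genes separated the groups completely, as did 670 of the tested genes (4.19%, where chance gives 2.86%). Atf3, Sprr1a, Mustn1, Ecel1, Jun and Sh2d3c stayed past the threshold in each alternative that tested them, whereas Prph reached an adjusted p of 0.232, Hrk 0.167, Stmn4 0.346, Dusp1 0.504, Mmp12 0.231 and Nms 0.129 in the least favourable one. None of these 6 changed sign, and their lowest log2 fold changes were 1.33, 1.15, 0.88, 0.68, 4.90 and 2.78.

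**Figure D1:**
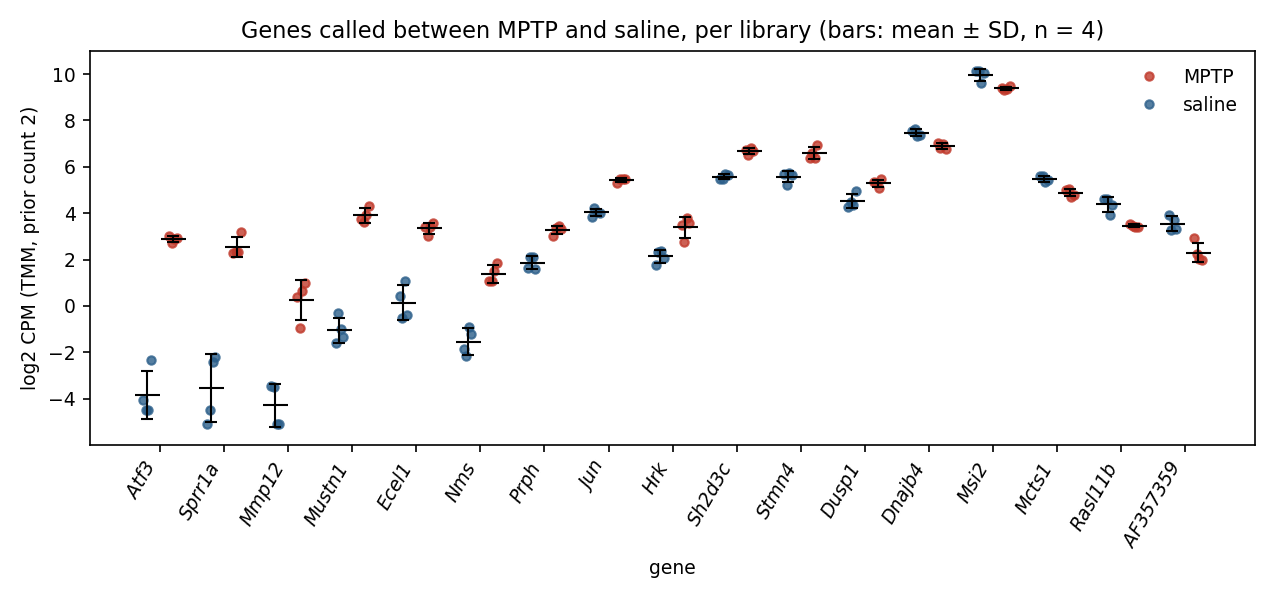
Log2 CPM (vertical axis) of the 17 called genes (horizontal axis) in each of the 4 MPTP and 4 saline libraries, ordered by log2 fold change, with points for libraries and bars for the group mean ± SD. Atf3 has the largest log2 fold change (7.06) and AF357359 the lowest (-1.23).

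The other 5 called genes were lower. Rasl11b, a small GTPase of the Ras family, fell from 21.3 ± 4.38 to 11.0 ± 0.510 CPM (SD, n = 4 each), a log2 fold change of -0.95 (adjusted p = 0.0123). The RNA-binding protein gene Msi2 (log2 fold change -0.60), the translation factor gene Mcts1 (-0.61) and the chaperone gene Dnajb4 (-0.59) had smaller falls. The small nucleolar RNA AF357359 had a log2 fold change of -1.23, but RefSeq gives it 30 bases on chromosome 12 (109650709 to 109650738), shorter than a read. Mcts1 has a retrocopy, and whether reads are shared with it was not tested, so the count of Mcts1 may be uncertain. Of the alternatives, 5 ended the call on Rasl11b, 10 that on Msi2, 8 that on Mcts1, 5 that on Dnajb4 and 8 that on AF357359, and the highest adjusted p values were 0.346, 0.380, 0.346, 0.503 and 0.269. With the non-neuronal score as a covariate Rasl11b (log2 fold change -0.76, adjusted p = 0.0513), Msi2 (-0.43, adjusted p = 0.0513) and Mcts1 (-0.58, adjusted p = 0.0860) no longer passed, although the fold of Mcts1 hardly changed. No lower gene was called by edgeR without MPTP 4 or without saline 1, although 527 and 434 lower genes there had an unadjusted p under 0.05. The number of lower genes was 4 without MPTP 1, 1 without MPTP 2, 2 without MPTP 3 and 3 without saline 2 or saline 4.

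The number of called genes changed most without saline 3. Without saline 3, edgeR called 138 genes higher and 159 lower, 297 in all, including all 17. Of these 138 genes, 15 were markers of non-neuronal cells, against 0 of the 12 with all 8 libraries. With all 8 libraries 107 of the 15999 tested genes were such markers, so 0 of 12 says little. DESeq2 on the 8 libraries called 25 higher and 30 lower, again including all 17. Of the 35 ways to split the libraries into 4 and 4, 2 gave 17 or more genes, the real split among them.

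Atf3 lies on chromosome 1 (191170296 to 191218039, minus strand) of GRCm38, Mustn1 on chromosome 14 (30879200 to 30881610, plus strand), Sprr1a on chromosome 3 (92483952 to 92485895, minus strand) and Ecel1 on chromosome 1 (87147655 to 87156521, minus strand). All are protein-coding, and their exons overlap no exon of another GENCODE gene. Jun (chromosome 4, 95049034 to 95052222, minus strand) shares 232 exonic bases, 7.30% of its own, with the antisense gene Junos. Sh2d3c (chromosome 2, 32721055 to 32755512, plus strand) shares 174 exonic bases with a protein-coding gene on the other strand. Mmp12 (chromosome 9, 7344381 to 7369499, plus strand) shares 157 with Mmp1b, also on the other strand.

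Genes of dopamine synthesis and identity did not pass the gene test with all 8 libraries. Th, the rate-limiting enzyme of dopamine synthesis, was at 2255 ± 315 CPM in MPTP and 2651 ± 550 CPM in saline (SD, n = 4 each), a log2 fold change of -0.23 (SE 0.14, adjusted p = 0.660). The dopamine transporter Slc6a3 had -0.23 (adjusted p = 0.618), the vesicular transporter Slc18a2 -0.15 (adjusted p = 0.777) and the decarboxylase Ddc -0.54 (adjusted p = 0.396). Aldh1a1, a marker of ventral nigral neurons, had -0.44 (adjusted p = 0.517), the transcription factor Satb1 -0.35 (adjusted p = 0.415) and the palmitoyltransferase Zdhhc8 0.11 (adjusted p = 0.757). Without saline 3, Slc6a3, Ddc, Aldh1a1 and Satb1 passed the threshold in the same direction, with lowest adjusted p values over all alternatives of 0.0463, 0.000468, 0.0132 and 0.0265. The highest over all alternatives were 0.981, 0.791, 0.944 and 0.987.

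Of the 48 gene lists, 13 were higher and 13 lower in MPTP by camera with the preset correlation. With the non-neuronal score as a covariate 6 were higher and 4 lower, and with an estimated correlation only the axon injury list passed. The axon injury and regeneration list was higher (adjusted p = 1.7e-17, and adjusted p = 0.00199 with an estimated correlation). Of its 41 tested genes, 5 rose over all genes tested, namely Atf3, Jun, Sprr1a, Ecel1 and Stmn4, and 12 rose and 1 fell when adjusted over the list alone. Its mean log2 CPM was 4.13 ± 0.03 in MPTP and 3.48 ± 0.06 in saline (SD, n = 4 each). Log2 fold changes were above 0 in 26 of its genes and below 0 in 15. Their median was 0.18 and their mean 0.65, as a few genes rose far more than the rest. With a mean CPM of at least 5 the median was 0.08.

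The immediate early list was also higher (adjusted p = 9.0e-11). It fell short with an estimated correlation (adjusted p = 0.0808). Of its 27 tested genes 3 rose, Atf3, Jun and Dusp1, and 4 rose when adjusted over the list alone. Jund had a log2 fold change of 0.82 and an adjusted p of 0.0552. The 2 members shared with the axon injury list are Atf3 and Jun, and without them the list still passed (adjusted p = 0.00497, an alternative added after seeing the data). Its median log2 fold change was 0.31, and 0.16 with the non-neuronal score as a covariate. With that covariate and without saline 3 the call ended (adjusted p = 0.143, median -0.15).

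**Figure D2:**
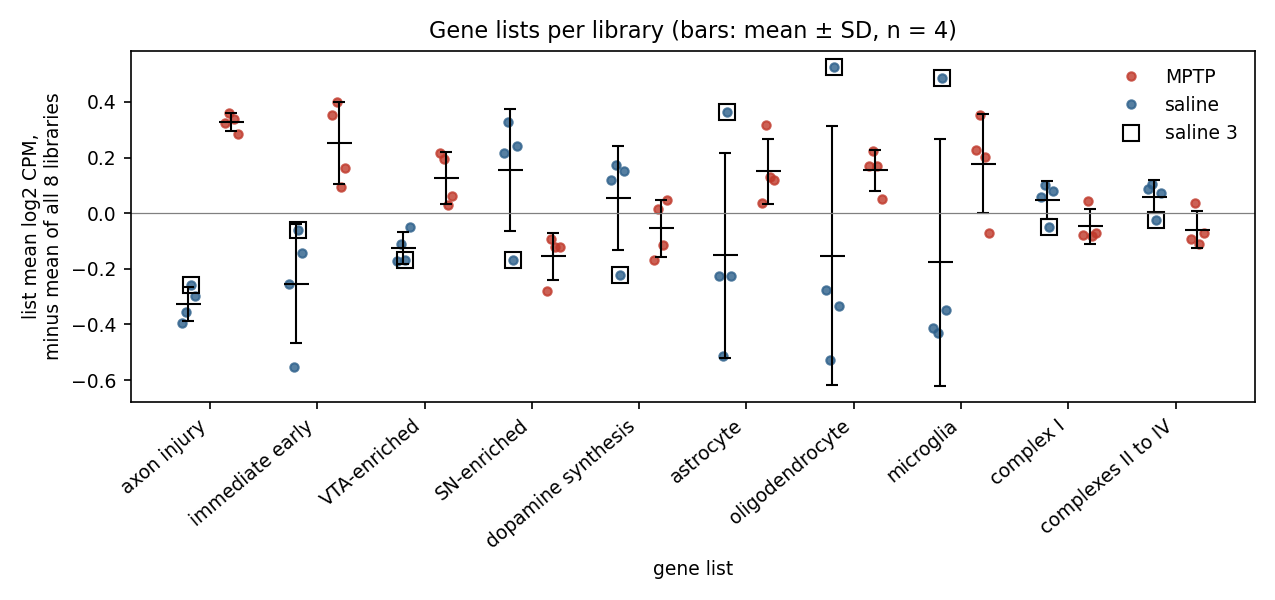
Mean log2 CPM of 10 gene lists in each library, less the mean of all 8 libraries (vertical axis), with points for the 4 MPTP and 4 saline libraries, bars for the group mean ± SD and an open square around saline 3. The axon injury list separates the groups, with MPTP at 4.09 to 4.17 and saline at 3.41 to 3.55 before the mean was taken off.

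Markers of dopaminergic subregions moved in opposite directions. The substantia nigra-enriched list was lower in MPTP, with 20 of its 21 genes below 0 and a median log2 fold change of -0.31 (adjusted p = 1.0e-12). It did not pass with an estimated correlation (adjusted p = 0.369). Its leading members were the vesicle GTPase gene Rab3c (-0.63), the secreted factor gene Ndnf (-0.53), the potassium channel gene Kcnj6 (-0.55) and the growth factor gene Fgf1 (-0.39), each with an adjusted p of 0.321. The ventral tegmental area-enriched list was higher, with 20 of 23 genes above 0 and a median of 0.31 (adjusted p = 3.4e-05, and adjusted p = 0.114 with an estimated correlation). Efnb3 (0.48, adjusted p = 0.357), Wnt7b (0.67), Cck (0.45) and Vip (0.52) led it, and none of them passed the gene test. Adjusted over the list alone, 10 substantia nigra genes fell and 1 rose, and 1 ventral tegmental gene rose. Saline 3 had the lowest substantia nigra score of the saline libraries, 6.12 against 6.50 to 6.61, beside its high non-neuronal score. Its nigral score lay within the MPTP range of 6.01 to 6.19, so the list score did not separate the groups. With the non-neuronal score as a covariate the nigral median was -0.15, and the list still passed with the preset correlation (adjusted p = 4.1e-06).

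Astrocyte, oligodendrocyte and microglia markers were higher in each MPTP library than in saline 1, 2 and 4, though not than in saline 3. The astrocyte list (26 of 26 genes above 0, median log2 fold change 0.25, adjusted p = 7.4e-06), the oligodendrocyte list (24 of 25, median 0.22, adjusted p = 7.4e-06) and the microglia and macrophage list (17 of 28, median 0.22, adjusted p = 0.0173) were higher in MPTP. None passed with an estimated correlation (adjusted p = 0.499 for each), and no member passed over all genes tested. Clu had a log2 fold change of 0.38, Galnt6 0.69, C1qc 1.05 and the lysosomal macrophage marker Cd68 2.04 (adjusted p = 0.169). Adjusted over the list alone, 1 astrocyte gene and 1 microglia gene rose and no oligodendrocyte gene did. Without saline 3 the medians were 0.47, 0.49 and 0.45. Endothelial and mural markers (median 0.04, adjusted p = 0.333), oligodendrocyte precursors (0.24, adjusted p = 0.0799), GABAergic neurons (0.08, adjusted p = 0.339) and glutamatergic neurons (0.18, adjusted p = 0.0930) did not pass. Without saline 3 the last 3 did (medians 0.49, 0.35 and 0.32, adjusted p = 0.000246, 0.000351 and 0.0184). None of these 3 passed there with an estimated correlation (adjusted p = 0.166, 0.195 and 0.255). With the non-neuronal score as a covariate the GABAergic list was lower (adjusted p = 0.00998). The haemoglobin list (median 0.35, adjusted p = 0.0212) and the nuclear noncoding RNA list (median 0.30, adjusted p = 0.0212) were higher as well, each with an adjusted p of 0.499 with an estimated correlation. With the non-neuronal score as a covariate the call on each of these 5 higher lists ended (adjusted p = 0.322 to 0.938), although that score is built partly from the astrocyte, oligodendrocyte and microglia lists themselves. The microglia call ended without MPTP 2, saline 1, saline 2 or saline 4, the haemoglobin call without MPTP 1, saline 2 or saline 4, and the noncoding call without MPTP 2, saline 2 or saline 4.

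The non-neuronal marker score was 2.61 ± 0.14 in MPTP and 2.34 ± 0.40 in saline (SD, n = 4 each), a difference of 0.27 on the log2 scale (exact permutation p = 0.229). The dopaminergic marker score was 7.69 ± 0.10 in MPTP and 7.83 ± 0.28 in saline (SD, n = 4 each), a difference of -0.14 (exact permutation p = 0.371). Saline 3 had the highest non-neuronal score of the 8 libraries (2.92) and the lowest dopaminergic score (7.42). Its nuclear RNA Malat1 was at 2194 CPM, against 475 to 945 CPM in the other saline libraries and 1049 to 1745 CPM in MPTP. Without saline 3 the differences were 0.47 for the non-neuronal score (exact permutation p = 0.0286, the smallest possible) and -0.28 for the dopaminergic score (exact permutation p = 0.0571).

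**Figure D3:**
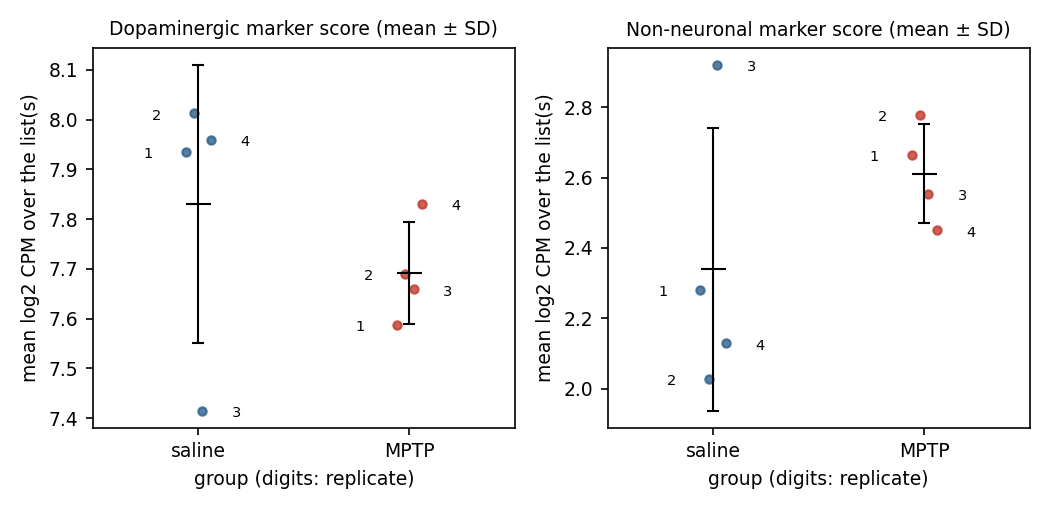
Dopaminergic (left) and non-neuronal (right) marker scores, as mean log2 CPM over the lists (vertical axes), for the 4 saline and 4 MPTP libraries, with replicate digits at the points and bars for the group mean ± SD. Saline 3 lies at 7.42 on the left and 2.92 on the right, outside the range of all other libraries.

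Lists of dopaminergic function were lower. The dopaminergic neuron marker list had 22 of 26 genes below 0 and a median log2 fold change of -0.14 (adjusted p = 0.000232), which was -0.26 without saline 3. Dopamine synthesis and handling (median -0.15, adjusted p = 0.0156) and dopaminergic transcription factors (median -0.15, adjusted p = 0.0319) were lower too, and no gene of these lists passed over all genes tested. Adjusted over the list alone, 2 genes of the marker list fell and 0 of the others did. With an estimated correlation the adjusted p was 0.499, 0.499 and 0.501. The call on dopamine synthesis ended without MPTP 1, MPTP 3, saline 2 or saline 4, and that on the transcription factors when any 1 library other than MPTP 4 or saline 3 was left out. With the non-neuronal score as a covariate none of the 3 lists passed. The adjusted p was then 0.322 for the markers, 0.938 for synthesis and 0.495 for the transcription factors, and the medians were 0.06, -0.02 and 0.05.

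Stress lists moved both ways. The list of endoplasmic reticulum chaperones had 22 of 27 genes above 0 (median 0.14, adjusted p = 0.000127), led by the disulfide isomerase genes Pdia4 (log2 fold change 0.39) and Pdia6 (0.41). The integrated stress response list had 22 of 37 above 0 (median 0.04, adjusted p = 0.00396), with Atf3 its 1 called gene and Chac1 (0.38) and the amino acid transporter gene Slc7a5 (0.30) next. Their adjusted p values with an estimated correlation were 0.460 and 0.439, and the second list did not pass without saline 3 (adjusted p = 0.0575) or with a mean CPM of at least 5 (adjusted p = 0.133), where Atf3 was not tested. The heat shock list was lower (16 of 23 below 0, median -0.10, adjusted p = 0.00269, and adjusted p = 0.499 with an estimated correlation), with Dnajb4 its 1 called gene and Hsf2 at -0.36. Adjusted over the list alone, 0 chaperone genes and 1 integrated stress response gene rose, and 1 heat shock gene fell. The heat shock call ended without saline 2 and with the non-neuronal score as a covariate (adjusted p = 0.339, median 0.02).

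Energy metabolism genes were slightly lower as groups. Nuclear complex I genes had 33 of 37 below 0 (median -0.09, adjusted p = 8.8e-05), led by Ndufa4 (-0.30) and Ndufb6 (-0.32). Genes of complexes II to IV had 23 of 25 below 0 (median -0.12, adjusted p = 4.9e-05), led by Uqcrb (-0.35) and cytochrome c, Cycs (-0.29). ATP synthase (median -0.12, adjusted p = 0.00108), the tricarboxylic acid cycle (-0.12, adjusted p = 0.00377) and glycolysis (-0.09, adjusted p = 0.0144) were lower as well. No member passed over all genes tested or when adjusted over the list alone, and the adjusted p with an estimated correlation was 0.499 for each of these lists. With the non-neuronal score as a covariate complex I (adjusted p = 0.0126) and complexes II to IV (0.00190) still passed, but ATP synthase (0.0886), the tricarboxylic acid cycle (0.322) and glycolysis (0.693) did not. The calls on ATP synthase and the tricarboxylic acid cycle also ended without saline 2, and that on glycolysis without MPTP 2, saline 1 or saline 4.

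Among other lists, synaptic vesicle genes (median -0.07, adjusted p = 0.00484), cholesterol synthesis (-0.10, adjusted p = 0.0105) and cytoskeleton and axonal transport (-0.09, adjusted p = 0.0141) were lower, although Stmn4 of the last rose and Sv2c of the first stood at -0.35. Cytosolic ribosomal proteins (70 of 79 genes above 0, median 0.10, adjusted p = 1.9e-05), neuropeptides (median 0.10, adjusted p = 0.0208) and cytokines and complement (median 0.22, adjusted p = 0.0358) were higher. Ribosomal protein genes such as Rpl21 (0.51) have many pseudogenes that can share reads, and Rpl15 stood at -0.29. The neuropeptide gene Vgf had 0.55. Adjusted over the list alone, 0 neuropeptide genes rose and 1, Fgf1 (-0.39), fell, and 0 cytokine genes passed. The called gene Nms is not in the neuropeptide list. With an estimated correlation the adjusted p was 0.369 for neuropeptides and 0.499 for the rest. Calls ended without MPTP 2, saline 1 or saline 2 for neuropeptides, cytokines and the cytoskeleton, without MPTP 1 for cytokines, cholesterol synthesis and ribosomal proteins, and without saline 4 for cholesterol synthesis. With the non-neuronal score as a covariate only the ribosomal proteins still passed (adjusted p = 0.0126), whereas synaptic vesicle genes (0.359, median -0.01), cholesterol synthesis (0.684, 0.00), the cytoskeleton (0.359, -0.04), neuropeptides (0.202, 0.13) and cytokines (0.684, 0.11) did not. The neuropeptide median did not shrink there. With a mean CPM of at least 5, neuropeptides (adjusted p = 0.0545) and cytokines (0.512) did not pass.

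Several lists that fit a mitochondrial toxin did not pass with all 8 libraries. These were apoptosis (adjusted p = 0.189), in which Hrk rose and Bcl2l11 stood at 0.42, p53 targets (0.409), oxidative stress defence (0.373), where Gpx3 stood at 0.50, NRF2 targets (0.662), interferon response (0.0842), microglial activation (0.137), reactive astrocytes (0.483), proteasome (0.336), autophagy and lysosome (0.336) and mitochondrial biogenesis (0.137). Parkinson disease-linked genes had a median of -0.06 (adjusted p = 0.0654), with Vps35 at -0.33, not past the gene test. Without saline 3, 5 of these lists passed, with interferon response (adjusted p = 0.0445) and microglial activation (0.0184) higher and proteasome (0.0202), autophagy and lysosome (0.0440) and Parkinson disease-linked genes (0.00493) lower. None of them passed there with an estimated correlation.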

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

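Of 164 groups of 4 values examined, 13 held a library that stood apart from the other libraries of its group, where chance gives about 8.2. In this part the tests of non-neuronal RNA, of activated glia, of dilution, of the neuron mix and of saline 3 were chosen only after the results were seen, and the count over splits was planned.

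Saline 3 lay below the other saline libraries in Slc6a3 (log2 CPM 11.29 against 11.82 to 11.88), in Slc18a2 (9.05 against 9.63 to 9.73), in the dopamine synthesis list (7.27 against 7.61 to 7.67) and in the dopaminergic marker list and score, which are the same values (7.42 against 7.94 to 8.01). It lay above them in the microglia list (0.84 against -0.08 to 0.00). MPTP 4 was high in Sprr1a (3.17 against 2.28 to 2.34), and MPTP 1 was low in Jun (5.28 against 5.46 to 5.47) and in the substantia nigra list (6.01 against 6.16 to 6.19). MPTP 2 was high in complex I (6.88 against 6.75 to 6.76) and in neuropeptides (3.07 against 2.86 to 2.89). Saline 1 was low in Pdia6 (4.00 against 4.39 to 4.45) and in endoplasmic reticulum chaperones (4.70 against 4.84).

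Of the 35 splits of the 8 libraries into 4 and 4, 2 gave 17 or more called genes (5.71%), the real one included, so chance cannot be excluded by this count; the highest other split gave 28, with MPTP 1, 2 and 3 beside saline 3. A larger share of RNA from non-neuronal cells is argued against as the whole cause for Atf3, Sprr1a, Mustn1, Ecel1, Jun and Sh2d3c. They stayed past the threshold with the non-neuronal score in the model, both with all libraries and without saline 3 (highest adjusted p = 0.0103). These 6 are the genes that passed in both fits, so the grouping follows from the test itself. With all libraries that score took the astrocyte median from 0.25 to 0.05, but it is built partly from that list. Without saline 3 the score left non-neuronal signal behind, so that fit is the weaker check. There the astrocyte median was 0.18, and the oligodendrocyte list still passed by camera with the preset correlation (median 0.34, adjusted p = 0.00978). For the other 11 genes it cannot be excluded, since each call ended in at least 1 of these fits (adjusted p up to 0.504). With the score and all libraries, Hrk, Rasl11b, Mcts1 and Msi2 lost the call and the rest kept it. Rasl11b went there from -0.95 to -0.76 and Msi2 from -0.60 to -0.43. With the score and without saline 3, all but Hrk lost the call. There the score itself separated the groups (2.45 to 2.78 in MPTP, 2.03 to 2.28 in saline). That fit could hardly tell the score from treatment, so a call lost there does not decide the cause. None of the folds there was smaller than with all libraries and no covariate, which differs by both changes. The SE grew, as in Dusp1 from 0.76 (SE 0.14) to 0.95 (SE 0.32). Induction inside glia or macrophages cannot be told apart from induction in neurons, since the activation lists (smaller adjusted p = 0.137, and 0.0184 for microglial activation without saline 3, where its median of 0.28 lay below the 0.45 of the microglia markers) need not hold the induced genes and RNA from the unbound fraction was not analysed here. A response of dopaminergic neurons to MPTP remains a hypothesis.

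The opposite moves of the substantia nigra and ventral tegmental lists were weighed next. Uniform dilution by RNA of other cells would lower the nigral list as much as dopamine synthesis genes, but with their 2 shared genes removed the nigral list fell by 0.22 more (log2, exact permutation p = 0.0286, the smallest possible). For the ventral tegmental list, camera with an estimated correlation and the non-neuronal score in the model gave an unadjusted p of 0.0123. That argues against RNA of non-neuronal cells as the whole source of the rise. The score holds no markers of other neurons, so RNA from those could not be tested in this way. When saline 3 was left out as well, the preset-correlation call on the ventral tegmental list ended (adjusted p = 0.399). Its median was unchanged at 0.31, as the median SE of its genes went from 0.18 to 0.36. The ventral tegmental minus nigral score was 0.56 higher in MPTP (exact permutation p = 0.0286), and both a different mix of nigral and tegmental neurons in the tissue taken and a change within or loss of nigral neurons predict that sign, so they cannot be told apart here. The effect of MPTP on these neurons stays open.

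The 297 genes called without saline 3 were weighed last. More RNA of other cells in saline 3 fits the values, since it was the highest saline library in 11 of 12 lists of other cell types, which may account for the rise in calls when it is left out. A wrong label is argued against, because the axon injury list score of saline 3 (3.55) lay 0.54 below the lowest MPTP library, where the MPTP libraries had an SD of 0.03. That test was added after a first count had not excluded a wrong label. The count covered 31 genes that the fit without saline 3 called higher by a log2 fold change of at least 1. In saline 3, 13 of them lay below the midpoint of the groups and 18 above. Whether RNA of other cells would also give such a split was not tested.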

How the results depend on the processing

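The alternatives that combine leaving out saline 3 with a covariate or an estimated correlation, and the immediate early list without shared genes, were chosen after seeing the data. For the 17 called genes, 224 of 285 alternative values stayed past the threshold, 61 did not and 0 changed sign. With DESeq2 25 genes were higher and 30 lower, with a mean CPM of at least 5 7 were higher (Atf3, Sprr1a, Mmp12 and Nms were then not tested), and with the non-neuronal covariate 3 were lower. Leaving out saline 3 with that covariate gave 7 higher and 11 lower, and 7 of the 17 remained. Leaving out 1 library gave 8 (without MPTP 4) to 138 (without saline 3) higher genes, 0 to 159 lower genes, 8 to 17 higher lists and 7 to 16 lower lists. Higher lists numbered 6 with the covariate, 1 with an estimated correlation, 2 with fry, 3 without saline 3 with the covariate and 1 without saline 3 with an estimated correlation. Lower lists numbered 4, 0, 0, 3 and 0 in the same order; camera with an estimated correlation gave 1 lower list at an unadjusted p under 0.05, fry 2, and the last setting 8. The dopaminergic score difference ranged from -0.28 to -0.08 and the non-neuronal one from 0.17 to 0.47 when 1 library was left out. Slc18a2 changed sign with the covariate (0.0737), as did the medians of the dopaminergic transcription factor (0.0540), dopaminergic marker (0.0558), oligodendrocyte (-0.0138), heat shock (0.0196) and cholesterol lists (0.000691), while the nuclear noncoding list turned by its test (median 0.0619). Without saline 3 and with the covariate, Zdhhc8 (-0.10), Vgf (-0.21) and the medians of the nuclear noncoding (-0.0734), immediate early (-0.147) and transcription factor lists (0.0306) changed sign. The cause was not tested for any of these. The replicate numbers did not pair the libraries (correlations of -0.02, -0.12, -0.03 and 0.04); the replicate block gave 10 higher and 4 lower genes, 13 of them among the 17, 14 higher and 13 lower lists, and score differences of -0.14 and 0.27 (exact sign-flip p = 0.375 for both). Genes with a few counts in saline, such as Mmp12, are limited by depth.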
